A study of Mus musculus with 8 samples.

How the data were processed

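RNA was measured in whole embryonic brains of 8 mice of the Ohia line, 3 mutants homozygous for mutant alleles of Sap130 and Pcdha9 and 5 littermate controls heterozygous for both. Per the labels' protocols, total RNA was isolated with a column kit that included DNase digestion on the column, and libraries were made with a TruSeq RNA kit. That kit selects polyadenylated RNA and does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart, and transcripts without a poly(A) tail, such as most histone transcripts, are measured poorly. Per the submitters' processing notes, the tools named were TopHat2 2.0.9, HTSeq 0.5.4p5 and edgeR 3.4.2 with the mouse builds mm10 and GRCm38, without a statement of which step each served.

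The deposited table holds expected counts, that is estimated reads per gene that are not normalised, for 34866 genes in 8 columns, and every column name matched a single sample title. Between 66.0% and 68.9% of the values in a column were whole numbers. HTSeq writes whole numbers only, so the counting step behind the deposited values is not given in the sources used here. Fractional values arise where reads that match several genes are shared out, so genes with near-identical copies carry an uncertainty that cannot be resolved from this table. This applies to ribosomal protein genes with many pseudogenes and to the alpha and gamma protocadherins, whose variants share constant 3' exons. The expected counts were rounded to whole numbers before testing. Column totals ranged from 36438282 to 47838448. The gene identifiers were matched to GENCODE M21 on GRCm38 by identifier without version for 34652 genes and with version for 32644, which gave symbols, coordinates and transcript sequences, and 214 identifiers received no symbol. The table covers 21850 protein-coding genes and 12300 pseudogenes, with 19 lincRNA genes.

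Groups were taken from the genotype and stage labels. The middle number of each sample title was read as a litter number, since the series text speaks of littermates, although the labels do not define it. Litter 260 is the E13.5 litter, and litters 195 and 303 are the E14.5 litters, so the stage comparison is also a comparison of 1 litter with 2 others. The reading was checked by correlating, over genes, the deviation of each mutant from the mutant mean with the deviation of its litter's controls from the control mean. The same-litter correlations were 0.313 for litter 260, 0.114 for litter 195 and 0.255 for litter 303, all above 0.1, and the numbers were treated as pairing the samples. Mutant 195-3 correlated more strongly, at 0.386, with the control of litter 303. Stage was not removed from these deviations and litter 260 is the only E13.5 litter, so its value can reflect stage. The check therefore cannot settle that the number is a litter number.

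Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the genotype groups with a minimum count of 10, which left 17357, and libraries were scaled with TMM factors. The main test was the edgeR quasi-likelihood F test with robust dispersion estimates, with stage and genotype in the model, and Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call. The common biological coefficient of variation was 14.27%. Stage was read from the same model, the dependence of the mutant effect on stage from its interaction term, and the difference between the E14.5 litters from a fit of the 5 E14.5 samples. Expression levels are given as CPM, the edgeR scaling of counts to TMM-adjusted library size, as mean ± SD, and values on the log2 CPM scale use a prior count of 2. Differences within a litter are the mutant minus the mean of its litter's controls on that scale. P-values measure the spread between individual embryos.

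Before the data were examined, 52 gene lists were fixed, of which 51 had at least 5 tested members. Each was tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 51 lists. The list tests for genotype and for stage over all samples were repeated with an estimated correlation and with fry, both from limma 3.58.1. The interaction list test was repeated with an estimated correlation alone. List tests under the alternatives below used the preset correlation only. The named genes were chosen by a rule fixed at the same time. It takes Sap130 and Pcdha9, the 10 genes of smallest p per direction for genotype that lay on 1 side in 3 of 3 litters and carry a standard symbol, and up to 4 members of each list that passed the threshold. For stage it takes 8 genes per direction and up to 3 members of each called list, and for the interaction up to 5 genes. In a called list with no passing member the 2 of smallest p stand as values. Some genes that this rule takes are not reported here. Genes outside this rule are marked in the text as chosen after their values were seen.

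The alternatives fixed beforehand were RLE and upper quartile factors, no filter, a filter of CPM of at least 1 in 3 samples, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test and the edgeR exact test. Also fixed beforehand were no covariate, litter as a replicate block, removal of erythroid and sex-linked genes, omission of each library in turn, and, for single genes and their counts only, the E14.5 samples alone. Further alternatives were chosen after seeing the data. The first is a per-library loess offset (span 0.5) on log2 length and GC content of the longest annotated transcript, which was known for 17288 tested genes (99.6%). The others are the omission of both libraries without Hox gene expression, the list tests in the E14.5 samples alone, and omission of each library for the interaction and litter counts. Intervals of list medians are 95% bootstrap intervals over genes from 2000 resamples and treat genes as independent. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

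The tests were tried on counts simulated from the real means and library sizes with 200 changed genes, 50 at each fold. For genotype, over 17178 genes, 26% of genes changed 1.3-fold were recovered, 60% at 1.5-fold, 72% at 2-fold and 94% at 4-fold, with 14 false calls among 140. For stage, over 17151 genes, the shares were 14%, 56%, 74% and 92%, with 11 false calls among 129. For the interaction, over 17176 genes, they were 0%, 4%, 24% and 76%, with 7 false calls among 59. For the E14.5 litters, over 17129 genes, they were 10%, 28%, 54% and 94%, with 22 false calls among 115. The false share exceeded the threshold of 0.05 in each of these comparisons. With no change simulated for genotype, over 17158 genes, 1 was called. Of the 51 lists, 5 were given a shift, and camera called all 5 of these and 2 others for genotype, and all 5 and 1 other for stage. Genes were simulated independently of each other, while the correlation estimated in the data was 0.462 for oxidative phosphorylation and 0.67 for ribosomal proteins. These counts therefore do not show how often camera calls falsely on correlated lists. With a simulated length trend over 17357 genes, the length and GC offset reduced false genotype calls from 951 to 13. Reads, alignments and allele sequences were not analysed here.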

Results

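The brains of 8 mouse embryos of the Ohia line were profiled by RNA-seq. Mice of this line that are homozygous for mutant alleles of Sap130 and Pcdha9 model hypoplastic left heart syndrome (HLHS), a congenital defect in which the left side of the heart is underdeveloped. Sap130 encodes a subunit of the SIN3-HDAC transcriptional repressor complex, and Pcdha9 encodes an alpha protocadherin, a neuronal cell adhesion protein. The design compares 3 homozygous mutants with 5 heterozygous littermate controls, from 1 litter at E13.5 (mutant 260-1 and controls 260-2 and 260-3) and 2 litters at E14.5 (mutant 195-3 with controls 195-2 and 195-6, and mutant 303-2 with control 303-3). Library totals were 45796572 counts in mutant 260-1, 39173060 in control 260-2, 43753194 in control 260-3, 47838448 in control 195-2, 44517310 in mutant 195-3, 45756870 in control 195-6, 36438282 in mutant 303-2 and 41942580 in control 303-3.

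Sap130 (ENSMUSG00000024260.13; GRCm38 chromosome 18, 31634371 to 31723061, plus strand, protein coding) was lower in each of the 3 mutants than in any control. Its level was 35.9 CPM in mutant 260-1, 34.6 in mutant 195-3 and 32.6 in mutant 303-2, against 49.9 in control 260-2, 46.8 in control 260-3, 51.6 in control 195-2, 49.0 in control 195-6 and 52.1 in control 303-3. The means were 34.4 ± 1.65 CPM (SD, n = 3) and 49.9 ± 2.14 CPM (n = 5), a log2 change of -0.54 (SE 0.07, adjusted p = 0.00291). Pcdha9 (ENSMUSG00000103770.1; chromosome 18, 36997880 to 37187657, plus strand, protein coding) was at 9.47 CPM in mutant 260-1, 18.2 in mutant 195-3 and 12.01 in mutant 303-2, and at 19.8, 14.9, 24.6, 20.6 and 21.2 CPM in controls 260-2, 260-3, 195-2, 195-6 and 303-3. The means were 13.2 ± 4.50 and 20.2 ± 3.52 CPM, a log2 change of -0.66 (SE 0.16, adjusted p = 0.0212), with mutant 195-3 above control 260-3. The Pcdha9 call was lost without mutant 260-1 (adjusted p = 0.0948), mutant 303-2 (0.0793) or control 195-2 (0.0649). The alpha protocadherin variants share constant exons, so the division of reads among them is uncertain.

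The comparison of mutants with controls asked how the brain transcriptome differs in the HLHS model. Of 17357 genes tested, 1885 were higher and 1691 lower in the mutants, together 20.6%. Most changes were small, with median log2 changes of 0.39 among the higher and -0.56 among the lower genes, and 350 genes changed at least 2-fold, 80 of them higher and 270 lower. Of the 3576 called genes, 3565 had the same sign in 3 of 3 litters, which selection by a test over the same litters favours. With upper quartile scaling the split became 1240 higher and 2090 lower. The count depends on the libraries used: it was 1058 higher and 1040 lower without mutant 260-1, 646 and 731 without mutant 303-2, 900 and 961 without control 260-2, 632 and 685 without control 195-2, and 786 and 805 without control 303-3.

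The higher genes of smallest p were led by the glycolytic enzymes Ldha (lactate dehydrogenase A) and Tpi1 (triosephosphate isomerase). Ldha was at 367 ± 26.1 CPM in mutants and 209 ± 11.3 CPM in controls (log2 change 0.81, SE 0.07, adjusted p = 0.00155). Tpi1 was at 371 ± 10.8 and 204 ± 21.3 CPM (0.87, SE 0.08, adjusted p = 0.00162). The homeodomain transcription factors Irx3 and Irx5, which pattern the neural tube, rose by log2 1.14 (SE 0.12) and 1.02 (SE 0.11). The chromatin reader Ing2, another SIN3-HDAC subunit, rose by 0.85 (SE 0.08). Cnpy1 and Shisa3 rose by 1.13 and 1.06, and the respiratory chain genes Ndufb6 and Atp5l by 0.73 and 0.68. Rps27rt, a retrogene copy of a ribosomal protein gene whose reads are hard to separate from its parent, rose by 0.90. The adjusted p of these genes lay between 0.00155 and 0.00177.

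The lower genes of smallest p were led by Tmem44, at 71.0 ± 10.3 CPM in mutants and 146 ± 11.9 CPM in controls (log2 change -1.07, SE 0.07, adjusted p = 0.000361). Hr, a nuclear receptor corepressor, was at 1.64 ± 0.0819 and 6.36 ± 0.955 CPM (-1.96, SE 0.14, adjusted p = 0.000445). Nos1, neuronal nitric oxide synthase, changed by -1.40 on the log2 scale (SE 0.10), Adora1, the adenosine A1 receptor, by -1.21 (SE 0.12) and Gramd1b by -1.19 (SE 0.08). Prkce, Shtn1 (a regulator of axon formation), Gpr21, Bend6 and the metalloproteinase inhibitor Timp2 changed by -0.86, -0.81, -0.92, -0.85 and -0.63. These 20 genes of smallest p passed the threshold under each alternative, except Timp2 (adjusted p = 0.0551) and Bend6 (0.0621) without the stage covariate.

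Gene lists of energy metabolism and protein synthesis were called higher in the mutants. In the hypoxia response list, which holds glycolytic enzymes and other targets of hypoxia-inducible factor, 27 of 42 tested genes rose and 2 fell (29 and 4 adjusted over the list alone), with a median log2 change of 0.34 (camera adjusted p = 3.995e-11). Besides Ldha and Tpi1, Eno1 rose from 418 ± 46.4 to 667 ± 16.8 CPM (log2 0.69) and Pgk1 from 239 ± 31.4 to 342 ± 24.4 CPM (log2 0.54). Of 61 nuclear genes of oxidative phosphorylation, 37 rose and 0 fell (51 and 0 over the list alone), median 0.35 (adjusted p = 6.194e-23), with Cox6c at log2 0.77. Of 48 ribosomal protein genes, 35 rose and 0 fell (46 and 0 over the list alone), median 0.44 (adjusted p = 2.156e-22), with Rpl34 at 0.77 and Rps19 at 0.67. Of 13 genes encoded in the mitochondrial genome, 5 rose and 0 fell (6 and 0 over the list alone), median 0.49 (adjusted p = 8.493e-05), with mt-Co3 at 0.73 and mt-Nd3 at 1.44. With an estimated correlation the adjusted p of each of these 4 lists was 0.433, and by fry the mitochondrially encoded genes missed the threshold (0.06778). The mitochondrial share of counts was 3.17%, 3.26% and 2.49% in mutants 260-1, 195-3 and 303-2 and between 2.05% and 2.57% in the controls. The share of pseudogenes was 1.22%, 1.08% and 0.99% in the same mutants and between 0.75% and 0.97% in the controls, and that of the 10 most abundant genes was 5.16%, 5.37% and 4.95% against 4.25% to 4.76%. The medians were positive in all 3 litters for each list. In litters 260, 195 and 303 they were 0.287, 0.394 and 0.249 for hypoxia response, 0.235, 0.321 and 0.503 for oxidative phosphorylation, 0.453, 0.211 and 0.652 for ribosomal proteins, and 0.739, 0.387 and 0.093 for mitochondrially encoded genes.

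Expression differences also ran with transcript length across all genes. The median log2 change was 0.20 in the tenth of genes with the shortest transcripts (median 855 bases) and -0.18 in the tenth with the longest (median 8219 bases). Pairs of controls from one litter also differed with length, from -0.16 to 0.16 between controls 260-2 and 260-3 and from -0.12 to 0.13 between controls 195-2 and 195-6. The median transcript length was 1046 bases for oxidative phosphorylation, 1114 for ribosomal proteins, 784 for mitochondrially encoded genes and 3260 for hypoxia response. With a length and GC offset in each library the medians of these lists were 0.21, 0.25, 0.32 and 0.36, each still called (adjusted p = 1.758e-10, 7.774e-13, 0.008205 and 9.47e-12). The members higher with the offset were 22 for oxidative phosphorylation, 18 for ribosomal proteins, 4 for mitochondrially encoded genes and 24 for hypoxia response, and those lower were 0, 1, 0 and 1.

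**Figure D1:**
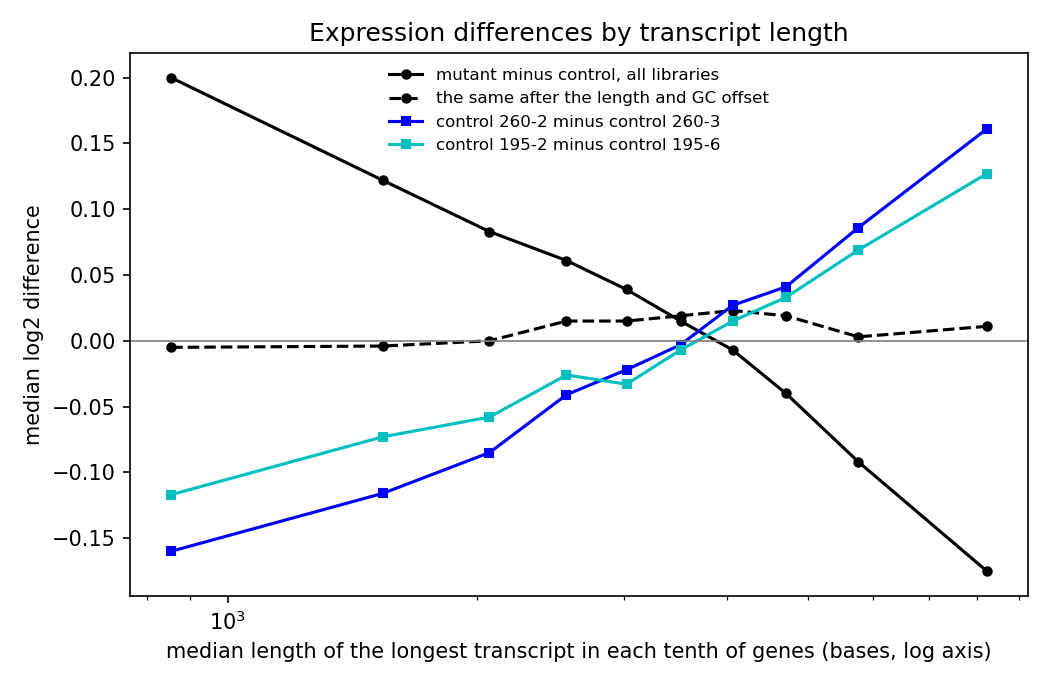
Median log2 difference (y axis) in 10 groups of genes ordered by the length of their longest annotated transcript (x axis, bases, log scale), for mutants minus controls before and after the length and GC offset and for pairs of controls of one litter. The mutant difference goes from 0.20 to -0.18 with length, and the control pairs also show a trend, whose sign depends on which control is subtracted.

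Synaptic and neuronal gene lists were called lower in the mutants. In the synaptic receptor and adhesion list 0 of 32 tested genes rose and 11 fell (12 over the list alone), median log2 change -0.28 (adjusted p = 2.254e-08), with litter medians of -0.34, -0.05 and -0.40 in litters 260, 195 and 303. Grin2b, the NMDA receptor subunit GluN2B, was at 87.1 ± 22.3 CPM in mutants and 187 ± 52.1 CPM in controls (log2 -1.15, SE 0.12, adjusted p = 0.00175). Gria1 (an AMPA receptor subunit) and the scaffold gene Shank2 changed by -0.79 and -0.76 on the log2 scale. Of 35 autism risk genes 0 rose and 19 fell (0 and 21 over the list alone), median -0.30 (adjusted p = 4.642e-09), with Adnp at -0.64 and Myt1l at -0.57 besides Grin2b. With an estimated correlation the adjusted p of both lists was 0.433, and by fry the synaptic list missed the threshold (0.0504). The members of these lists have long transcripts (medians 7589 and 7202 bases), and with the length and GC offset their medians were -0.15 and -0.11, still called (adjusted p = 0.0001043 and 0.00246), with 9 and 5 members lower and 1 and 0 higher.

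Of 29 pan-neuronal genes 1 rose and 10 fell (1 and 11 over the list alone), median -0.22 (adjusted p = 0.001096; 0.629 with an estimated correlation). The microtubule protein gene Dcx changed by -0.41, the RNA-binding protein genes Rbfox3 and Elavl3 by -0.41 and -0.33 and the synaptic vesicle gene Syn1 by -0.56 on the log2 scale. Of 32 targets of REST, the repressor of neuronal genes, 1 rose and 12 fell (1 and 14 over the list alone), median -0.18 (adjusted p = 0.001096; 0.609 with an estimated correlation), with Vgf at -0.77. Both lists had medians near 0 in litter 195 (0.00 and 0.05) and lost their call without mutant 260-1 (adjusted p = 0.171 and 0.084), by fry (0.1033 for both) and in the E14.5 samples alone (0.2531 and 0.1565), and the pan-neuronal call was lost with the 6 libraries that express Hox genes (0.07839). With the length and GC offset REST targets had a median of -0.104 with 4 members lower and 1 higher (adjusted p = 0.0188), and pan-neuronal genes had a median of -0.19 with 8 lower and 1 higher (0.0007646). Of 38 axon guidance genes 2 rose and 11 fell (2 and 11 over the list alone), median -0.14 (adjusted p = 0.004616; 0.433 with an estimated correlation). The semaphorin receptor genes Plxna4 and Nrp1 changed by -0.85 and -0.52, the netrin receptor gene Unc5a by -0.61 and Draxin by -0.43. This call was lost with the length and GC offset (adjusted p = 0.330), where the median was -0.021 with 5 members higher and 7 lower.

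Pcdha9 belongs to the clustered protocadherins, of which the alpha and beta lists were called lower and the gamma list was not. Of 13 alpha genes 0 rose and 8 fell (0 and 10 over the list alone), median -0.55 (adjusted p = 2.533e-05), with Pcdha11 at -0.77, Pcdhac2 at -0.61 and Pcdha3 at -0.55. Of 21 beta genes 0 rose and 10 fell (0 and 11 over the list alone), median -0.55 (adjusted p = 3.547e-06), with Pcdhb13 at -1.09 and Pcdhb21 at -0.84. With an estimated correlation the adjusted p was 0.433 for both lists. Among 22 gamma genes 3 rose and 4 fell (3 and 5 over the list alone), median -0.20 (adjusted p = 0.214), with Pcdhgc3 at -0.48 and Pcdhga9 at 0.41. The alpha and beta medians were -0.68 and -0.79 in litter 260, -0.30 and -0.11 in litter 195, and -0.72 and -0.64 in litter 303.

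Genes that mark the thalamus and midbrain were higher in mutants of all 3 litters. Of 24 tested genes 16 rose and 0 fell (18 and 0 over the list alone), median log2 change 0.59 (adjusted p = 5.141e-12; 0.433 with an estimated correlation). The midbrain homeobox genes En2 and En1 rose by 0.93 (SE 0.10, adjusted p = 0.00206) and 0.67 (SE 0.10), the thalamic gene Lhx9 by 0.66 (SE 0.09), and Pou4f1 from 35.8 ± 7.26 to 75.2 ± 12.2 CPM (log2 1.11, SE 0.16). The litter medians were 0.26 in litter 260, 0.86 in litter 195 and 0.64 in litter 303. In the Cajal-Retzius list, which includes genes shared with the midbrain and hindbrain, 6 of 11 genes rose and 1 fell (7 and 3 over the list alone), median 0.73 (adjusted p = 0.01009; 0.433 with an estimated correlation). Nhlh2 and Barhl2 rose by 0.81 and 0.87, while Reln, the reelin gene that defines Cajal-Retzius cells, fell by 0.53. Without mutant 195-3 this call was lost (adjusted p = 0.102). Of 19 forebrain patterning genes 2 rose and 1 fell (4 and 1 over the list alone), and the list was not called (median 0.26, adjusted p = 0.276; called higher without mutant 195-3, 0.0006051), with litter medians of 0.51, -0.27 and 0.36. Otx2, a gene of both forebrain and midbrain, rose by 0.76 and Vax1 fell by 1.13.

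Libraries differed sharply in genes of single brain regions. The following genes outside the fixed rule were chosen after their values were seen. The dorsal telencephalon genes Emx1 and Tbr1 were at 3.45 and 12.7 CPM in mutant 195-3, below the lowest control values of 22.55 and 109.62. In mutant 303-2 they were at 31.65 and 50.97 CPM, so Emx1 lay within the control range there. Over 20 telencephalon genes the median log2 difference from litter controls was -2.66 (95% interval -2.88 to -1.19) in litter 195, -1.22 (-2.06 to -0.38) in litter 303 and 0.12 (-0.01 to 0.32) in litter 260. Of 15 Hox genes, which are expressed in the hindbrain and spinal cord, the median level was 0.02 CPM in mutant 260-1 and 0.09 CPM in control 195-6, and between 7.11 and 16.5 CPM in the other 6 libraries.

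**Figure D2:**
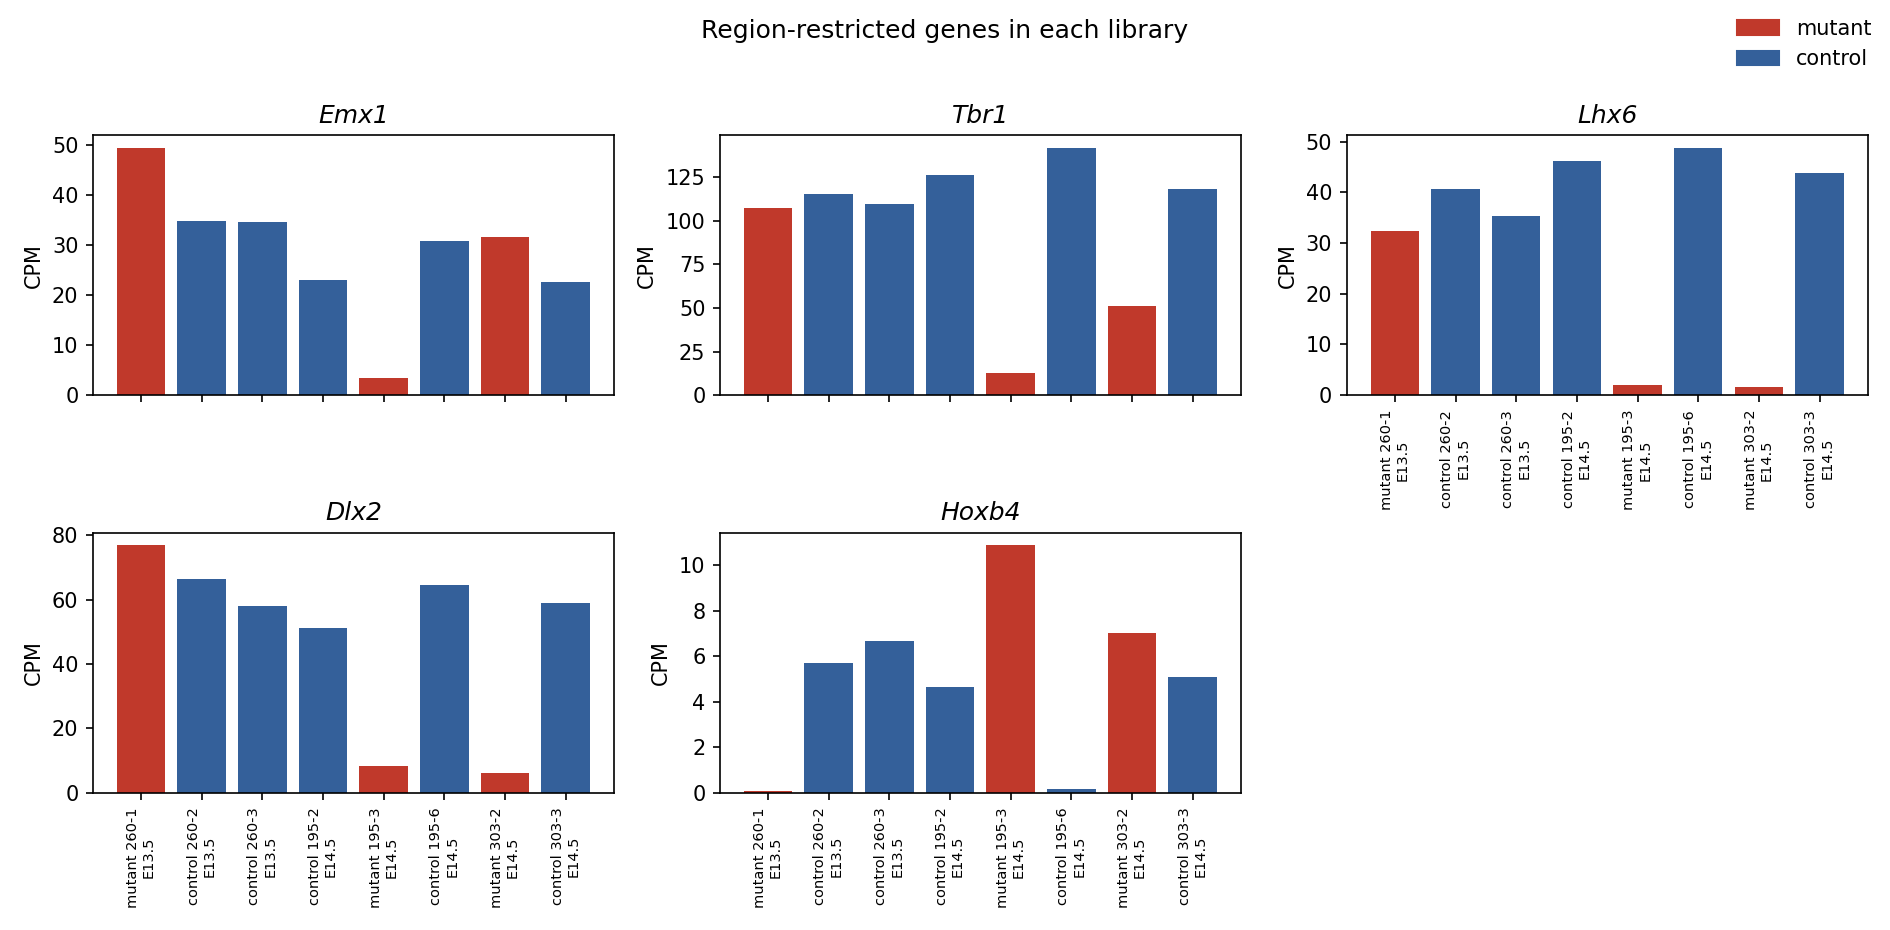
Level (CPM, y axis) of 5 region-restricted genes in each of the 8 libraries (x axis), with mutants in red and controls in blue and 1 bar per library. Emx1 and Tbr1 are lowest in mutant 195-3, Lhx6 and Dlx2 are lowest in mutants 195-3 and 303-2, and Hoxb4 is near 0 in mutant 260-1 and control 195-6.

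The list tests over all litters reflect these differences between libraries only in part. Of 24 excitatory cortical neuron genes 1 rose and 5 fell (1 and 6 over the list alone), median -0.47 (adjusted p = 0.003553; 0.46 with an estimated correlation and 0.05334 by fry), and Cux2 fell from 87.0 ± 6.32 to 53.4 ± 6.40 CPM. The medians of this list were -0.08, -0.75 and -0.30 in litters 260, 195 and 303, so the shift was near 0 in litter 260. Bcl11b, at 106 ± 45.3 and 206 ± 12.3 CPM, fell by 0.98 (adjusted p = 0.0261), a call lost without mutant 303-2 (0.122), control 195-2 (0.0703) or control 303-3 (0.0589), and with the length and GC offset (0.0643). Of 24 genes of the ganglionic eminences and inhibitory neurons 2 rose and 2 fell, also over the list alone, median -0.35 (adjusted p = 0.01632; 0.629 with an estimated correlation and 0.1151 by fry). Foxp1 and Meis2 changed by -0.41 and -0.27 and Gsx1 rose by 0.82. The litter medians of that list were 0.12, -0.45 and -0.69 in litters 260, 195 and 303, and the call was lost without mutant 303-2 (adjusted p = 0.132) or control 195-6 (0.05997). Of 29 hindbrain and cerebellum genes 1 rose and 1 fell (1 and 0 over the list alone) and the list was not called (median 0.30, adjusted p = 0.536), with litter medians of -3.76, 2.27 and 0.44. Without the 2 libraries that lack Hox expression, an alternative chosen after seeing the data, this list was called higher (adjusted p = 9.989e-13). In that fit 984 genes were higher and 986 lower, 848 and 841 of them shared with the full set. The list was also called higher without mutant 260-1 (adjusted p = 8.738e-06) and in the E14.5 samples alone (2.325e-05). Both of these fits keep control 195-6, whose missing hindbrain expression lowers the control side and favours such a call. The same control enters the litter 195 median of 2.27.

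**Figure D3:**
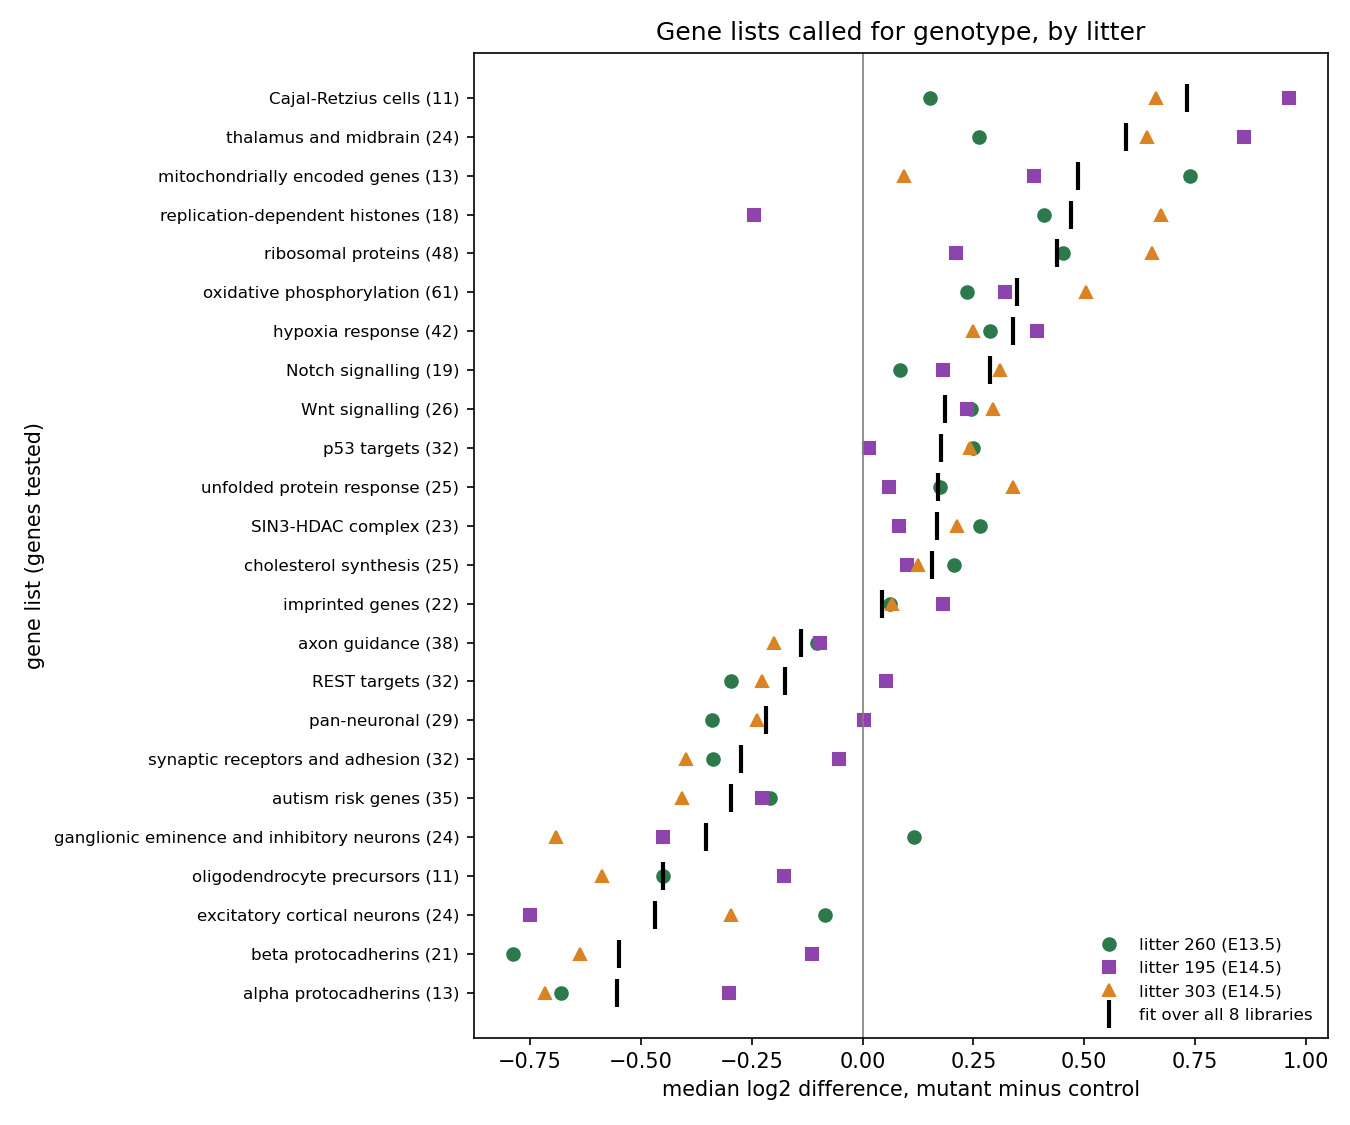
Median log2 difference between mutant and litter controls (x axis) for the 24 gene lists called for genotype (y axis, tested genes in parentheses), with a symbol for each litter and a black bar for the fit over all 8 libraries. Hypoxia response, oxidative phosphorylation, ribosomal proteins and thalamus and midbrain lie above 0 in each litter, and alpha and beta protocadherins and autism risk genes lie below 0 in each.

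Among the 23 tested genes of the SIN3-HDAC complex, the complex of Sap130, 8 rose, 2 fell and 13 did not pass (11 and 2 over the list alone), median 0.17 (adjusted p = 0.0008686; 0.433 with an estimated correlation), a call lost in the E14.5 samples alone (adjusted p = 0.06005). Ing1 rose from 75.7 ± 3.81 to 117 ± 14.8 CPM (log2 0.63) and Sin3a, the scaffold of the complex, from 83.2 ± 5.55 to 114 ± 17.5 CPM (log2 0.46). In Wnt signalling 9 of 26 genes rose and 0 fell (10 and 0 over the list alone), median 0.19 (adjusted p = 0.00352; 0.433 with an estimated correlation), with the receptor gene Fzd10 at 1.25, the Wnt secretion gene Wls at 0.52 and Nkd1 at 0.49. In Notch signalling 5 of 19 rose and 1 fell (8 and 2 over the list alone), median 0.29 (adjusted p = 0.01975; 0.433 with an estimated correlation), with the effectors Hes5 at 0.90 and Hes1 at 0.51 and the ligand gene Jag1 at 0.51. The Notch call was lost without mutant 303-2 (adjusted p = 0.0608), without the stage covariate (0.08017) and in the E14.5 samples alone (0.06896).

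Further lists were called for genotype. Of 25 unfolded protein response genes 4 rose and 0 fell, also over the list alone, median 0.17 (adjusted p = 0.002523; 0.462 with an estimated correlation), with Sec61b at 0.70 and Selenok at 0.38. Of 25 cholesterol synthesis genes 7 rose and 1 fell, also over the list alone, median 0.16 (adjusted p = 0.00832; 0.433 with an estimated correlation), with Sqle at 0.27 and Idi1 at 0.34. Of 32 p53 targets 7 rose and 1 fell (9 and 1 over the list alone), median 0.18 (adjusted p = 0.01632; 0.433 with an estimated correlation), with Rps27l at 0.74 and the stress-induced gene Sesn2 at 0.68. Of 22 imprinted genes 6 rose and 1 fell (7 and 1 over the list alone), median 0.05 (adjusted p = 0.03007; 0.433 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1c at 0.92, Ndn at 0.72 and Dlk1 at 0.77. Of 11 oligodendrocyte precursor genes 1 rose and 3 fell (1 and 8 over the list alone), median -0.45 (adjusted p = 0.00832; 0.433 with an estimated correlation), with the myelin gene Mbp at -0.47 and the ventral patterning gene Nkx2-2 at 0.72. Of 18 replication-dependent histone genes 5 rose and 0 fell, also over the list alone, median 0.47 (adjusted p = 0.04329; 0.712 with an estimated correlation), with Hist1h3a at 0.707 ± 0.390 against 0.228 ± 0.0874 CPM. Without mutant 260-1 the calls of p53 targets (adjusted p = 0.0885), cholesterol synthesis (0.0885) and histones (0.316) were lost, and that of imprinted genes was lost without mutant 195-3 (0.166) or control 195-6 (0.05997). The histone call was also lost without control 260-2 (0.119), control 260-3 (0.0506), control 303-3 (0.0540) or mutant 303-2 (0.0518), with the length and GC offset (0.273), without the stage covariate (0.08373) and by fry (0.1853). In the E14.5 samples alone the calls of p53 targets (0.1398), cholesterol synthesis (0.1044) and histones (0.3152) were lost as well, and so they were with the 6 libraries that express Hox genes (0.127, 0.2323 and 0.1856).

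Proliferation and progenitor lists were not called for genotype. Of 41 G1/S genes 1 rose and 0 fell (median 0.13, adjusted p = 0.0885) and of 53 G2/M genes 1 rose and 0 fell (median 0.10, adjusted p = 0.456), with litter medians of 0.49, -0.50 and 0.31 and of 0.59, -0.81 and 0.20 in litters 260, 195 and 303. Without mutant 195-3 both lists were called higher (adjusted p = 7.558e-10 and 9.531e-13), and without control 195-6 the G1/S list alone was (0.01142). In the E14.5 samples alone the G2/M list was called lower (0.002718). Of 22 radial glia genes 7 rose and 2 fell (median 0.14, adjusted p = 0.189; 0.00336 without mutant 195-3), with Vim at 0.42 and Ddah1 at -0.44. Of 17 intermediate progenitor genes 3 rose and 1 fell (median 0.20, adjusted p = 0.471; 0.0109 without mutant 195-3), with the proneural gene Neurog1 at 0.84.

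Markers of blood vessels, blood and other non-neural tissue were mostly not distinguishable. Of 27 endothelial genes 4 rose and 0 fell (median 0.13, adjusted p = 0.0701), among them the hypoxia-responsive ligand gene Apln, which rose from 9.97 ± 1.93 to 18.3 ± 4.03 CPM (log2 0.86), and Pecam1 at 0.34. The endothelial list was called higher without mutant 260-1 (adjusted p = 0.00312), control 260-3 (0.0175) or mutant 303-2 (0.0416), in the E14.5 samples alone (0.002323), with the 6 libraries that express Hox genes (0.01931) and without the stage covariate (0.03517). Of 22 erythroid genes 2 rose and 2 fell (median 0.01, adjusted p = 0.729), the embryonic globin genes Hbb-y and Hbb-bh1 rising by 1.52 (SE 0.37, adjusted p = 0.0347; 0.0567 with the litter block and 0.0613 with the length and GC offset) and 1.98 (SE 0.47, adjusted p = 0.0190). Of 22 microglia and macrophage genes 0 rose and 3 fell (median -0.06, adjusted p = 0.535; the list was called lower without mutant 303-2, 0.04164), with P2ry12 at -0.63. No call was made for mural cells (0 rose and 0 fell of 14), meninges and mesenchyme (1 and 1 of 28), choroid plexus (4 and 1 of 22), skeletal muscle (0 and 1 of 20), cartilage and bone (1 and 4 of 15), surface epithelium (0 and 0 of 14), lens and retina pigment epithelium (1 and 2 of 14), pituitary (2 and 0 of 9) or peripheral ganglia and neural crest (2 and 3 of 23), with adjusted p between 0.120 and 0.887. Some of these lists were called under an alternative. Meninges and mesenchyme were higher without mutant 260-1 (adjusted p = 0.02451) and in the E14.5 samples alone (0.02185), and mural cells in the E14.5 samples alone (0.03555). Called lower were cartilage and bone without mutant 303-2 (0.04164) and without the stage covariate (0.04162), surface epithelium without mutant 303-2 (0.02426), peripheral ganglia and neural crest without control 195-6 (0.02791), and choroid plexus without mutant 195-3 (0.01). For choroid plexus the median was -0.17 while the test pointed up, and for pituitary the median was -0.11, the mean 0.04 and the test pointed up.

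Of the remaining lists, Shh signalling (4 rose and 0 fell of 18, median 0.13, adjusted p = 0.135; called higher without mutant 195-3, 0.009782, and with the length and GC offset, 0.01803) included the floor plate gene Foxa2, which rose by 0.97. Of 29 apoptosis regulators 7 rose and 1 fell (adjusted p = 0.0757; called higher by fry, 0.03131), with Bmf at 0.83 and Hrk at -0.87. Of 25 immediate early genes 2 rose and 5 fell (adjusted p = 0.194; called lower with the 6 libraries that express Hox genes, 0.0484), with Fosl2 at -1.45 and Nr4a3 at -0.94. Holoprosencephaly genes (2 rose and 1 fell of 19), primary microcephaly genes (2 and 2 of 25), the integrated stress response (2 and 1 of 32), heat shock (4 and 2 of 20) and DNA methylation enzymes (2 and 4 of 16) had adjusted p between 0.347 and 0.711. Primary microcephaly genes were called lower without mutant 260-1 (adjusted p = 0.02437) and in the E14.5 samples alone (0.003106), with litter medians of 0.35, -0.42 and -0.06 in litters 260, 195 and 303. For heat shock the median was 0.06 and the mean -0.05. Tgif1, a holoprosencephaly gene, rose by 0.83 (SE 0.10). The list of sex-linked transcripts had 3 tested members, too few for the list test. All 3 were lower in mutants (median log2 change -2.45) and lower at E14.5 than at E13.5 (-3.41), and none passed the threshold for either comparison. Embryo sex was not in the model, so an unequal sex of the groups remains possible, and removing these genes as an alternative does not correct for it.

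The comparison of stages asked how the brain differed between E13.5 and E14.5, with 1 litter at E13.5. At E14.5, 389 genes were higher and 176 lower than at E13.5. The higher genes of smallest p were Car8 (log2 change 1.31, SE 0.12, adjusted p = 0.015), the calcium sensor gene Ncald (0.70, SE 0.08), the kinase gene Camk2b (0.70, SE 0.08) and Slc13a3 (1.08, SE 0.13). Bend6, Timp2, Dlgap3 and Sh3gl2 were higher by 0.68, 0.46, 0.61 and 0.54. Lower genes were led by Btg3 (-0.91, SE 0.11, adjusted p = 0.0253), the chromatin protein gene Hmga2 (-1.20, SE 0.15), the histone mRNA binding gene Slbp (-0.44), the securin gene Pttg1 (-1.06), E2f2 (-1.03), Fndc3c1 (-1.49), Ribc1 (-1.04) and Nuak2 (-0.53). The counts fell to 14 higher and 6 lower without mutant 260-1, to 10 and 0 without control 260-2, and to 0 and 0 without control 260-3, control 195-2 or control 303-3, at which 4100, 3248 and 3475 genes had an unadjusted p under 0.05. They rose to 743 and 579 without mutant 195-3, to 936 and 483 without control 195-6, and with DESeq2 to 1423 and 941.

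Among cell cycle and synaptic genes few single genes passed for stage, while their lists were called by camera alone. Of 41 G1/S genes 0 rose and 5 fell (0 and 40 over the list alone), median -0.58 (adjusted p = 4.705e-24; 0.467 with an estimated correlation), with Gmnn at -0.93 and Nasp at -0.44. Of 53 G2/M genes 0 rose and 1 fell (also over the list alone), the lamin B receptor gene Lbr at -0.59, median -0.73 (adjusted p = 9.756e-20; 0.488 with an estimated correlation). Of 32 synaptic genes 9 rose and 0 fell (27 and 0 over the list alone), median 0.37 (adjusted p = 4.088e-17; 0.467 with an estimated correlation), with Dlg2 at 0.61 and Grin2b at 0.66. REST targets (5 rose of 32, 18 over the list alone, median 0.31, adjusted p = 4.488e-11) and pan-neuronal genes (2 of 29, 21 over the list alone, median 0.28, adjusted p = 3.018e-10) were called higher, each at 0.467 with an estimated correlation, with Syn1 at 0.53 and Syp at 0.42. Of 13 alpha protocadherins 3 rose (11 over the list alone), median 0.55 (adjusted p = 1.266e-07; 0.467 with an estimated correlation). Of 22 radial glia genes 0 rose and 6 fell (3 and 9 over the list alone), median -0.38 (adjusted p = 2.696e-05; 0.467 with an estimated correlation), with Hes1 at -0.58, Pax6 at -0.56 and Prom1 at -0.49. In Notch signalling 0 of 19 rose and 4 fell (1 and 8 over the list alone), median -0.23 (adjusted p = 1.043e-05; 0.467 with an estimated correlation), with the ligand genes Dll1 at -0.64 and Dll3 at -0.65. By fry, none of the 25 lists called for stage passed (lowest adjusted p = 0.0765).

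Vascular lists were called higher at E14.5, with 3 of 27 endothelial genes higher (Slco1c1 at 0.73, Cldn5 at 0.57, adjusted p of the list 0.001474; 0.55 with an estimated correlation) and 2 of 14 mural cell genes higher (Rgs5 at 0.40, Higd1b at 1.02, adjusted p of the list 0.000925; 0.488 with an estimated correlation). Both calls were lost without mutant 260-1 (adjusted p = 0.113 and 0.0794) and with the 6 libraries that express Hox genes (0.1038 and 0.08264). Beta protocadherins (median 0.44) and gamma protocadherins (0.22), meninges and mesenchyme (0.26), autism risk genes (0.06) and oligodendrocyte precursors (0.23) were also called higher, with 0, 1, 1, 5 and 1 members past the threshold. Called lower were ribosomal proteins (median -0.19, 0 members past the threshold), intermediate progenitors (-0.42), forebrain patterning (-0.55), holoprosencephaly genes (-0.28), primary microcephaly genes (-0.29), histones (-0.58), the SIN3-HDAC complex (-0.14), Shh signalling (-0.21), the ganglionic eminence list (-0.46) and p53 targets (-0.10). With an estimated correlation the adjusted p of these 15 lists was at least 0.467. The call of meninges and mesenchyme was lost without mutant 260-1 (adjusted p = 0.3448) or mutant 303-2 (0.06599), that of autism risk genes without control 260-3 (0.5065) and with the length and GC offset (0.5141), and that of oligodendrocyte precursors without control 260-2 (0.05224). The call of the ganglionic eminence list was lost without mutant 260-1 (0.6455) or mutant 303-2 (0.1234) and with the 6 libraries that express Hox genes (0.2038), and that of p53 targets without mutant 260-1 (0.09587) and with the 6 libraries (0.1529). The other 26 lists were not called, among them hypoxia response (median -0.01, adjusted p = 0.634), oxidative phosphorylation (-0.04, adjusted p = 0.229) and thalamus and midbrain (-0.05, adjusted p = 0.9595). Several of them were called under an alternative. Oxidative phosphorylation was called lower with the 6 libraries (adjusted p = 2.53e-05) and without mutant 260-1 (0.002217), control 260-2 (0.02762) or control 195-6 (0.0487). Without mutant 260-1 and with the 6 libraries, thalamus and midbrain (0.0004602 and 0.0004368), Cajal-Retzius cells (0.01487 and 0.04316), hindbrain and cerebellum (0.00274 and 0.006964), erythroid genes (0.0004602 and 0.003685) and Wnt signalling (0.00943 and 0.01032) were called lower and excitatory cortical neurons higher (0.0001232 and 0.004783; 0.003766 without mutant 195-3). Hindbrain and cerebellum genes were called higher without control 260-2 (0.01249), control 260-3 (0.01761) or control 195-6 (0.003176). Microglia and macrophages were called higher, and DNA methylation enzymes lower, without control 260-3 (0.001323 and 0.01195), control 195-2 (0.03062 and 0.03851), mutant 195-3 (0.03245 for both) or control 303-3 (0.01983 and 0.0229), and with the length and GC offset (0.01296 and 0.001761). Mitochondrially encoded genes were called higher without mutant 260-1 (0.007128) and with the offset (0.04998), and pituitary lower without mutant 260-1 (0.01599). Axon guidance was called higher without control 260-2 (0.0235), and choroid plexus (0.02103), skeletal muscle (0.03594), surface epithelium (0.01627) and peripheral ganglia (0.01607) without control 260-3.

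Changes with stage and changes in the mutants ran in opposite directions for many genes. Of the genes higher at E14.5, 243 were lower in the mutants, where independent lists of these sizes would share 37.9, and 2 were higher, where 42.2 would be shared. Of the genes lower at E14.5, 55 were higher in the mutants (19.1 for independent lists) and 4 lower (17.1). Both sets of calls come from the same fit, and the E14.5 controls enter both comparisons. Independence is therefore not a fair baseline for these overlaps, and no overlap was simulated with shared libraries. Over 17357 genes, which are not independent replicates, Pearson's r between the mutant and stage differences was -0.36, against -0.05 in simulations with no effect that keep the shared libraries. The covariance was -0.0509 against -0.0032 in the simulations, and 65.6% of genes had opposite signs. Contrasts built with no library in common gave r between -0.15 and -0.31.

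The interaction of stage and genotype asked whether the mutant effect differed between E13.5 and E14.5, with 1 mutant at E13.5, which the test assumes to vary like the other samples. It was called for 18 of 17357 genes, and 1622 had an unadjusted p under 0.05. Among them were genes of the inhibitory neuron lineage of the ventral telencephalon. Camera called the ganglionic eminence list lower in the interaction, among other lists (adjusted p = 1.953e-50), a call lost with an estimated correlation (0.1551). Lhx6 was at 2.08 and 1.70 CPM in mutants 195-3 and 303-2 and at 32.3 CPM in mutant 260-1, against 35.4 to 48.8 CPM in controls (interaction log2 -4.37, adjusted p = 2.313e-05). Dlx2 was at 8.42, 6.07 and 76.95 CPM in the same 3 mutants, against 51.1 to 66.2 CPM in controls (-3.31, adjusted p = 0.0008397). Lhx8 and Dlx5 had interaction values of -5.90 and -2.95. The count was 6 without control 260-2, 80 without control 195-6, 121 without mutant 195-3 and 1051 without mutant 303-2, and 242 with DESeq2. Between the E14.5 litters 303 and 195, 0 of 17415 genes passed by the quasi-likelihood test, with 501 at an unadjusted p under 0.05, against 11 with DESeq2, 0 with limma-voom and 18 with the likelihood ratio test. Without mutant 195-3, 51 genes passed, and 3 passed without control 195-2.

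The plot of globin genes shows the level of Hbb-y in each library. It was 123 CPM in mutant 260-1 and 93.6 and 91.5 CPM in its litter controls. At E14.5 it was 25.8 CPM in mutant 195-3 and 27.8 CPM in mutant 303-2, against 4.40, 7.26 and 6.99 CPM in controls 195-2, 195-6 and 303-3.

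**Figure D4:**
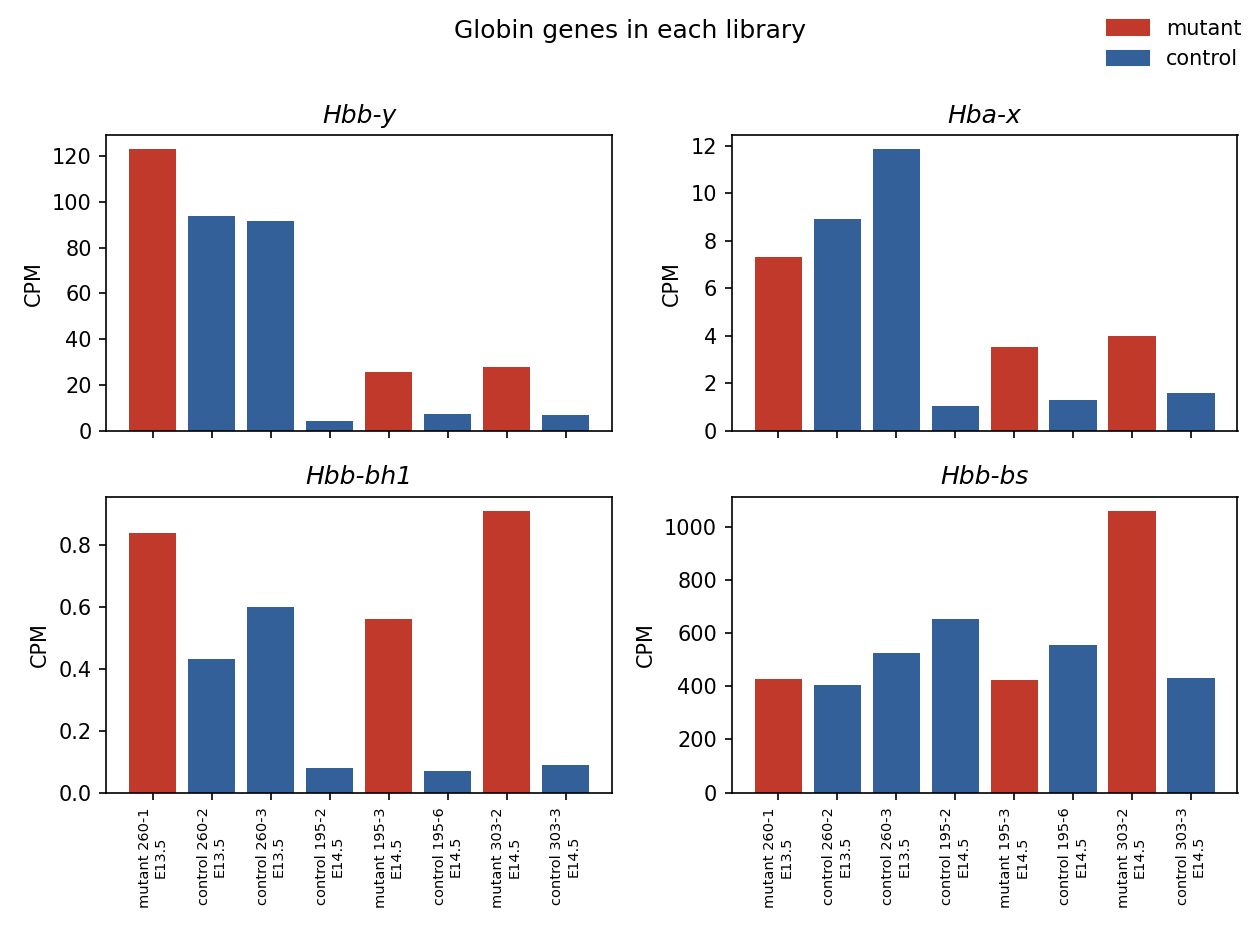
Level (CPM, y axis) of the embryonic globin genes Hbb-y, Hba-x and Hbb-bh1 and the adult-type globin gene Hbb-bs in each of the 8 libraries (x axis), mutants in red and controls in blue, 1 bar per library; Hba-x and Hbb-bs were chosen after their values were seen. The embryonic globins are higher in both E14.5 mutants than in the E14.5 controls, while Hbb-bs is higher in mutant 303-2 and not in mutant 195-3.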

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

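The tests on Hox genes, on telencephalon genes and on the share of midbrain and thalamus, and the length and GC offset, were chosen after the result was seen.

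Among 241 values checked in the 5 controls, 6 had 1 control library standing apart, and chance flags about 1 in 20 groups. Ldha was at 228 CPM in control 260-3 and 200 to 207 CPM in the other controls, and the mean log2 CPM of the hypoxia response list was 5.60 there, against 5.50 to 5.52. Ing1 was at 69.0 CPM in control 195-2, against 77.0 to 78.0. In control 195-6, mt-Co3 was at 3398 CPM, against 2750 to 2875, and Ddc at 11.8 CPM, against 9.63 to 10.1. The mean log2 CPM of the hindbrain and cerebellum list was -0.15 in control 195-6, against 2.97 to 3.33 in the other controls.

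The interaction test called a difference of the mutant effect between stages for 18 genes, and for 6 to 1051 without 1 library. The interaction log2 values were -4.37 for Lhx6, -5.90 for Lhx8, -3.31 for Dlx2 and -2.95 for Dlx5. E13.5 holds 1 mutant, which the test assumes to vary like the other samples. With 1 litter at E13.5, a difference between stages and a difference between litters are confounded here.

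The first pattern is the loss of whole sets of regional genes from some libraries. Ventral telencephalon genes were lower in both E14.5 mutants, with medians of -2.66 in mutant 195-3 and -2.79 in mutant 303-2, against 0.31 in mutant 260-1. Mutant genotype as the cause of the missing Hox expression in mutant 260-1 is argued against by control 195-6, where the median log2 Hox difference from the other controls was -5.76. Loss of the telencephalon as a whole is consistent with mutant 195-3, whose dorsal and ventral telencephalon genes were lower alike (dorsal minus ventral median -0.34), and is argued against in mutant 303-2, where dorsal genes stayed 2.55 log2 units above ventral ones. Tissue lost at dissection could take a whole region, and a malformed ventral telencephalon could give the pattern of mutant 303-2. The labels describe neither the dissection nor the brain anatomy, so both remain open for the telencephalon as hypotheses.

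The second pattern is the rise of thalamus and midbrain genes in all 3 litters. A length and GC trend as the whole cause is argued against by the median of 0.66 that remained with the offset. Control 195-6 also lacked Hox expression, and its median for these genes was 0.075 (95% interval -0.08 to 0.20). In mutant 260-1 the median was 0.26 (0.17 to 0.50), so the intervals overlap. Absence of hindbrain tissue as the cause in mutant 260-1 is therefore argued against only weakly, and on 1 control. A larger share of midbrain and thalamus in the mutant samples was taken to predict lower telencephalon genes in every litter. They were lower in litters 195 and 303 (medians -2.66 and -1.22, intervals below 0). The highest litter median was 0.12, in litter 260, with an interval that reaches below 0. Mutant 260-1 lacked Hox expression, and absent hindbrain tissue could raise the shares of telencephalon and midbrain together, so litter 260 cannot test this prediction. A larger share therefore cannot be told apart from a change within the tissue, and a biological change in these regions remains untested.

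The third pattern is the rise of short-transcript lists and the fall of long-transcript ones. A length and GC trend, as far as the offset captures it, is argued against as the whole cause by the medians that remained with the offset, each with an interval that excludes 0. These were 0.21 for oxidative phosphorylation (95% interval 0.14 to 0.26), 0.25 for ribosomal proteins (0.20 to 0.33), 0.32 for mitochondrially encoded genes (0.03 to 0.54), -0.15 for synaptic genes (-0.21 to -0.05) and -0.11 for autism risk genes (-0.16 to -0.01). The trend may account for part of each shift, since the medians without the offset were 0.35, 0.44, 0.49, -0.28 and -0.30. The offset used the longest annotated transcript, which need not be the one expressed, so some genes may be corrected too little. The simulated length trend used the same lengths and could not show this. Hypoxia response, with a median length of 3260 bases, is not a short-transcript list, and its median was 0.34 without the offset and 0.36 (0.24 to 0.43) with it, which argues against the trend as its cause too. RNA quality differences between libraries, not given in the labels, remain open.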

How the results depend on the processing

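The length and GC offset, the omission of both libraries without Hox expression and the E14.5-only list tests were chosen after seeing the data, and the cause was not tested unless stated. Genes higher and lower in mutants stayed within 1.5 times of 1885 and 1691 under RLE factors, no filter, the CPM filter, DESeq2, limma-voom, the likelihood ratio test, removal of erythroid and sex-linked genes, the length and GC offset, and with litter as the replicate block (1382 and 1316). They moved further with upper quartile factors for the higher genes (1240), with the exact test (1145 and 913), with no covariate (890 and 588), with the 6 libraries that express Hox genes (984 and 986) and in the E14.5 samples alone with a litter block (237 and 341), where fewer samples were fitted. Leaving out 1 library gave 632 to 2517 higher and 685 to 2467 lower. Of 181 named genes called for genotype, 161 passed with the litter block, 158 with the length and GC offset, 115 with no covariate, 74 in the E14.5 samples alone and 54 under every setting, and 0 changed sign. Of all 3576 genotype calls, 2647 were shared with the litter block and 929 were lost, among them Hbb-y. The 24 list calls for genotype all passed with the block. The numbers of list members that rose or fell come from the main fit and were not recounted with the block.

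Stage counts of 389 higher and 176 lower became 193 higher with upper quartile factors, 648 and 313 with no filter, 1423 and 941 with DESeq2, 971 and 560 with the likelihood ratio test, 607 and 408 with the length and GC offset, and 21 and 7 with the 6 libraries. Leaving out 1 library gave 0 to 936 and 0 to 579. The 18 interaction genes became 242 with DESeq2 and 192 with the likelihood ratio test, and 6 to 1051 without 1 library. The 0 genes between E14.5 litters became 11 and 18 by these tools, and 0 to 51 without 1 library.

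The 24 lists called for genotype became 0 with an estimated correlation and 18 by fry, 17 of them shared, and 23 to 29 without 1 library. The 25 lists for stage became 0 with an estimated correlation and 0 by fry, and 23 to 31 without 1 library. A list direction turned with a call for choroid plexus, lower without mutant 195-3 (adjusted p = 0.01, and up to 0.9541 without 1 library), and for G2/M genes, lower in the E14.5 samples alone (0.002718). For stage, without mutant 260-1 and with the 6 libraries, 4 lists turned to lower: Cajal-Retzius cells (0.01487 and 0.04316, up to 0.9057 without 1 library), thalamus and midbrain (0.0004602 and 0.0004368, up to 0.935), hindbrain and cerebellum (0.00274 and 0.006964, up to 0.4045) and erythroid (0.0004602 and 0.003685, up to 0.8638). Depth of 36438282 to 47838448 counts limits genes near or below 1 CPM, such as Hist1h3a, more than the others.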

Other observations

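The tests on the embryonic globins and on shared libraries reported here were chosen after the result was seen.

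Embryonic globins were higher in both E14.5 mutants, while adult-type globins were lower in litter 195 and higher in litter 303. Hba-x, the embryonic alpha-like globin gene, chosen after its values were seen, was at 3.54 and 4 CPM in mutants 195-3 and 303-2 and at 1.05, 1.31 and 1.58 CPM in the E14.5 controls. Hbb-bh1 was at 0.56 and 0.91 CPM against 0.08, 0.07 and 0.09 CPM. The adult-type genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, also chosen afterwards, differed by -0.43 to -0.61 on the log2 scale in litter 195 and by 0.997 to 1.297 in litter 303. The interaction of stage and genotype was not called for Hbb-y (1.70, adjusted p = 0.0978).

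Some genes passed the threshold for both stage and genotype. Bend6 and Timp2 stand among the first genes for both comparisons, higher at E14.5 and lower in mutants, and Camk2b, higher at E14.5 by log2 0.70, changed by -0.81 in mutants (adjusted p = 0.00173). Fndc3c1 and Nuak2, lower at E14.5, were higher in mutants by 1.79 and 0.63.

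One hypothesis is that mutant brains or embryos lag behind their littermates. Hbb-y, which was lower at E14.5 than at E13.5, was higher in both E14.5 mutants, and more blood in the samples predicts that adult-type globins rise with it. Their median change averaged 0.30 over the E14.5 litters and went opposite ways in the 2 litters, so this cannot be told apart from a change in globin type. A younger age in all stage-dependent genes predicts higher G1/S genes in both E14.5 mutants, and the litter medians averaged -0.10 with opposite signs (-0.50 and 0.31), which leaves it open, as telencephalon genes were also lower in mutant 195-3. The opposition of mutant and stage changes may be part of the same pattern. Shared libraries as its cause are argued against by r of -0.15 or lower in each contrast with no library in common, and a length and GC trend by r of -0.14 or lower after both were regressed out. A delay therefore remains a hypothesis, with E13.5 represented by 1 litter.

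Other splits of the 8 samples into 3 and 5 show how far chance can be excluded. For genotype, 1 of the 55 splits that could be fitted gave as many as 3576 genes, the real one, and the highest other gave 367, so a count of that size did not arise from regrouping these samples. That highest other split set the 3 E14.5 controls apart, which with stage in the model contrasts controls and mutants within E14.5. The remaining splits leave the mutant difference in the residual spread, which lowers their counts. Among the 18 splits that take 1 sample of each litter, the highest other gave 1 gene, and no share smaller than 1 of 18 was possible. For stage, 1 of 55 splits gave as many as 565 genes, the real one, and the highest other gave 4. The real stage split sets 1 whole litter apart from the others, so its count cannot separate stage from litter. Embryos of a litter are not independent replicates of stage, so these splits cannot exclude chance for a stage effect. For lists, 22 of 55 splits gave at least the 24 called for genotype (highest other 33), and 28 of 55 gave at least the 25 called for stage (highest other 33), so chance is not excluded for the number of lists called. Within litters, 7 of 18 splits gave as many lists as the real one. The camera p of the hypoxia response list was matched in 2 of 55 splits including the real one, that of oxidative phosphorylation in 3, of ribosomal proteins in 4, of thalamus and midbrain in 5, of synaptic genes in 6 and of the ganglionic eminence list in 28. Among the 18 splits within litters the corresponding numbers, again with the real one, were 1, 2, 2, 2, 3 and 10, which are larger shares than over all splits for each of these lists. The smallest share possible there is 1 of 18, so for hypoxia response no other split within litters matched the real one.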
